A study of Mus musculus with 4 samples.

How the data were processed

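Leukocytes from B16-F10 tumours of 4 groups of mice were measured by 5′ droplet single-cell RNA sequencing, with 1 library per group from 6 pooled mice. Per the labels' protocols, tumours were mashed through a filter, red blood cells were lysed, and live CD45+ cells were sorted by SYTOX Blue exclusion, with no enzyme step named. Per the file headers and the submitters' processing notes, the authors made the matrices with Cell Ranger 7.0.0 on the GRCm38 mouse genome build. The deposited values are raw UMI counts per gene and barcode, with no normalization. The annotation release, the cell-calling settings and whether intronic reads were counted are not given in the sources used here. Intronic reads would add UMIs mainly to long genes, and whether they would do so alike in all libraries was not examined. Coordinates were taken by Ensembl identifier from the GENCODE vM21 annotation of GRCm38.

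The libraries held 8132 (control), 8313 (CD40), 10158 (PD1) and 10091 (combination) barcodes, all with at least 500 UMIs. Cells with at least 300 genes and at most 10% of UMIs from the 13 mitochondrial genes were kept, 7847, 7906, 9938 and 9720 in number. Doublets were scored per library with Scrublet as run in scanpy 1.11.5. The automatic threshold was 0.653 in the control library, where it marked 1 cell, and 0.329, 0.337 and 0.307 in the CD40, PD1 and combination libraries, where it marked 123, 260 and 296. A score of 0.25 was therefore used for all libraries, a choice made after the automatic thresholds were seen. It removed 201, 208, 426 and 399 cells. Kept cells had a median of 11296, 14596.5, 11593.5 and 13016 UMIs and 3160, 3646, 3169 and 3437 genes.

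The 4 libraries were clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Each cluster took the name of the marker list with the highest mean log2 ratio to the median of the clusters (5 CPM added), if that score was at least 1 and at least 3 markers had a log2 ratio of at least 1. Clusters of T cells were clustered again and named with the CD8, CD4, Treg and gamma-delta lists. A cluster stayed unnamed if its 10 leading genes held more markers of another class than of its own, if its cells had few UMIs and its leading genes none of its own markers, or if its median doublet score was at least 0.15. Cells took their cluster's name, and monocytes and macrophages were joined as mononuclear phagocytes because they grade into each other. Shares were taken of immune-like cells, which leaves out melanoma-like and unnamed cells, with exact Clopper-Pearson intervals. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

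Within a class, UMIs were summed per library and given as CPM with exact Poisson intervals, and log2 ratios with exact conditional binomial intervals. A count under 3 was set to 3 and its ratio called a bound, while intervals used the counts themselves. Because cells are not replicates, no test was run and no number of changed genes is given. The 5 classes with at least 100 cells in every library were compared. The 19 gene lists were fixed before the files were seen: MHC class I and class II presentation, type I interferon response, interferon gamma response, costimulation and CD40 signalling, dendritic cell maturation, inflammatory myeloid, suppressive macrophage, cytotoxic effector, T cell exhaustion, naive and stem-like T cell, T helper 1, regulatory T cell function, proliferation, T cell chemoattraction, glycolysis and hypoxia, dissociation stress, melanoma transcripts and treatment targets. Members needed at least 10 UMIs over the 4 libraries. A list's value is the median log2 ratio of its members, with an interval from 2000 Poisson redraws of the counts and its percentile among 10000 random lists of the same size, drawn in 20 bins of expression.

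Genes chosen by size were at 50 CPM and 30 UMIs or more in the higher library, and at 0.2 times or more of the CPM of the class with the highest level in that library, which keeps out free RNA. For each antibody they were ranked by the smaller of their log2 ratios in its 2 comparisons, which had to have the same sign and a size of at least 1, and up to 5 per direction were named. For combination against control, they were ranked by the bound of the interval nearest 0. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, sex-linked markers and predicted gene models were left out of this choice. Members of the fixed lists and markers of clusters are named outside it. Genes of close paralog families (Gzmd to Gzmg, Stfa2, Cstdc5, Ifit genes) are uncertain, since reads can be assigned to either copy.

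The steps were tested on simulated data drawn as Poisson counts from each class's pooled profile at the depth of each library, with 200 genes changed by known amounts in the libraries with CD40 antibody. The 95% intervals covered the true ratio for 95.9%, 96.8%, 96.2%, 96.2% and 96.2% of genes, CD40 against control, in mononuclear phagocyte-like, neutrophil-like, CD8 T-like, Treg-like and NK-like cells, and no unchanged gene was named. This checks the computation under counting error only. The simulated libraries held no variation between pools of mice and no shift of clusters within a class. False names from those sources were therefore not tested.

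Alternatives fixed before the data were examined were, for shares, a stricter filter (500 genes, 5% mitochondrial UMIs), doublets kept, Leiden resolutions 2 and 0.5, each library clustered on its own, cells thinned to 2000 UMIs before clustering, all kept cells as the denominator, and each cell named on its own. For lists they were the same apart from the denominator and the naming of single cells, with median-ratio scaling, a mean over cells, no minimum for list members, and a minimum of 100 UMIs. For genes they were median-ratio scaling, a mean over cells and doublets kept. Median-ratio scaling and the correlations across genes used the genes of a class with at least 100 UMIs in each library. Chosen after seeing the data were 8 settings. These were the values without neutrophil cluster 17 (shares, lists and genes), without neutrophil cluster 29 (the same; it has the highest doublet scores), and, for lists, without the monocyte-named clusters, without the macrophage-named clusters, without cluster T7 and without cluster 26. The others, for lists and genes, were Treg-like cells without those that have a Cd8a or Cd8b1 UMI and NK-like cells without those that have a Cd3e UMI. For shares, cells left out were also taken from the denominator. Not compared within the class were dendritic cell-like, CD4 T-like, B-like, pDC-like and gamma-delta T-like cells, which had too few cells. T cell receptor sequences were not analysed here beyond gene counts of the variable segments.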

Results

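B16-F10 is a transplantable mouse melanoma line. Mice with B16-F10 tumours received an antibody to CD40, a costimulatory receptor of antigen-presenting cells and B cells, injected into the tumour, or dilution buffer in its place. They also received an intravenous antibody to PD1, an inhibitory receptor of activated T cells, or IgG. Treatments were given on days 8 and 11, and tumours were taken on day 14. Live CD45+ cells, that is, leukocytes, were sorted from the tumours of 6 pooled mice per group and made into 1 droplet-based 5′ single-cell RNA library per group. The 4 libraries were a control (buffer and IgG), a CD40 library, a PD1 library and a combination library with both antibodies. The deposited values were unique molecular identifier (UMI) counts for 32285 genes. The libraries held 8132, 8313, 10158 and 10091 barcodes in that order, with 117735875 to 164755549 UMIs in total and a median of 11111.5, 14126, 11713 and 12928 UMIs per barcode.

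After filtering and removal of predicted doublets, 7646, 7698, 9512 and 9321 cells remained in the control, CD40, PD1 and combination libraries. Clusters were named by marker genes, and each name means only that the cells resembled the type ("CD8 T-like"). Predicted doublets were 2.56%, 2.63%, 4.29% and 4.10% of the filtered cells. Melanoma-like cells, which expressed the pigment genes Pmel, Dct and Tyrp1, made up 0.811%, 0.870%, 0.421% and 0.408% of the kept cells. Clusters left unnamed, because their leading genes were markers of another class or their cells had few UMIs, held 3.40%, 2.73%, 2.89% and 2.32%. The largest of them, cluster T6, expressed Tcf7, Ikzf2 and Klra genes and held 2.71%, 1.48%, 2.21% and 1.04%. Cluster T18, a cycling cluster with Tox and Pdcd1, held 0.589%, 0.117%, 0.305% and 0.0858%. The unnamed T cell clusters T6, T13 and T18 all scored highest on the CD8 T list. Unnamed cells numbered 260, 210, 275 and 216, beside 818, 1777, 1127 and 3056 CD8 T-like cells. Counting these clusters as CD8 T would make the differences in the CD8 T-like share below smaller, by an amount not computed. Their cells, with Tcf7 in T6, are also missing from the gene levels of that class. Shares below are percentages of the 7324, 7421, 9197 and 9067 immune-like cells. Each group was 1 library, so there was no spread between replicates to compare with and no difference was tested. Ranges in parentheses are 95% intervals (exact Clopper-Pearson for shares, exact Poisson for CPM, the UMIs of a gene scaled to those of its class) and cover counting error only. Gene levels were compared within a class as CPM, with UMIs summed over its cells, in the 5 classes with at least 100 cells in every library. Dendritic cell-like, CD4 T-like, B-like, pDC-like and gamma-delta T-like cells were too few for that.

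The CD40 antibody was seen in a pair of comparisons with no library in common, CD40 against control and combination against PD1. In both, dendritic cell-like cells were far scarcer and CD8 T-like and neutrophil-like cells more frequent with the antibody, while regulatory T (Treg)-like cells were scarcer. Dendritic cells, which carry tumour antigen to T cells, were 11.2% (10.5 to 11.9%) of immune-like cells in the control and 0.849% (0.653 to 1.08%) in the CD40 library, 13.2-fold lower. They were 6.72% (6.22 to 7.25%) in the PD1 and 0.485% (0.353 to 0.651%) in the combination library, 13.8-fold lower. CD8 T-like cells, the cytotoxic lymphocytes, were 11.2% (10.5 to 11.9%) in the control and 23.9% (23.0 to 24.9%) in the CD40 library, and 12.3% (11.6 to 12.9%) in the PD1 and 33.7% (32.7 to 34.7%) in the combination library. These were 2.14-fold and 2.75-fold differences. Treg-like cells, marked by Foxp3, made up 6.74% (6.18 to 7.34%) of the control and 2.18% (1.86 to 2.54%) of the CD40 library, and 5.14% (4.70 to 5.61%) of the PD1 and 1.89% (1.62 to 2.19%) of the combination library. Neutrophil-like cells made up 3.80% (3.37 to 4.26%) and 9.58% (8.92 to 10.3%) in the first comparison and 2.53% (2.22 to 2.88%) and 16.2% (15.4 to 16.9%) in the second. In the second, these were 6.38-fold higher, and 3.89-fold higher with cluster 17, which had 8 cells in the PD1 and 603 in the combination library, left out of the class.

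All 3 dendritic subsets were lower in the CD40 library than in the control. Cross-presenting cDC1-like cells (Xcr1, Clec9a) numbered 171 in the control, 4 in the CD40, 93 in the PD1 and 1 in the combination library. Over all barcodes, in the same order, Xcr1 had 1545, 70, 1227 and 106 UMIs and Clec9a 2553, 415, 3094 and 692. The cell counts may therefore overstate the loss. The cDC2-like cells (Cd209a, Clec10a) numbered 444, 29, 441 and 20, and mature dendritic cell-like cells (Ccr7, Fscn1) 203, 30, 84 and 23. B-like cells were 3.48% (3.07 to 3.93%) of the control and 0.755% (0.571 to 0.979%) of the CD40 library, and 1.65% (1.40 to 1.93%) of the PD1 and 0.474% (0.343 to 0.638%) of the combination library. CD4 T-like cells stood at 2.29%, 0.350%, 1.44% and 0.430% in the control, CD40, PD1 and combination libraries, and pDC-like cells at 1.04%, 0.377%, 1.08% and 0.143%. NK-like cells stood at 7.07% (6.50 to 7.68%), 6.59% (6.04 to 7.18%), 7.61% (7.08 to 8.17%) and 7.17% (6.65 to 7.72%). Gamma-delta T-like cells numbered only 4, 9, 5 and 9. The size of the dendritic difference depended on naming. For the share of dendritic cell-like cells, CD40 against control, the log2 ratio was -3.72 in the clusters used here, -4.71 with each library clustered on its own and -1.44 with each cell named on its own. The share of pDC-like cells, CD40 against control, turned from -1.46 to 0.21 with each library clustered on its own.

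**Figure D1:**
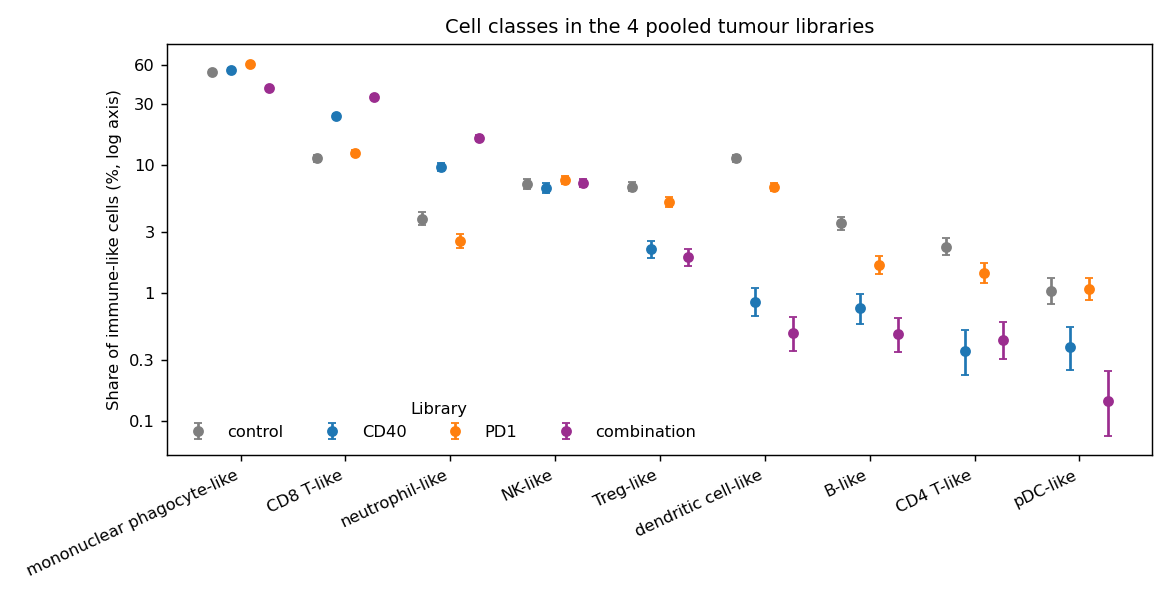
Share of immune-like cells (percent, log axis) in each named class for the control, CD40, PD1 and combination libraries, 1 pooled library each; error bars are exact 95% intervals for counting error. Dendritic cell-like cells lie at 0.849% and 0.485% in the libraries with CD40 antibody, against 11.2% and 6.72% in those without.

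In mononuclear phagocyte-like cells, the monocytes and macrophages, the share of the class was 53.2% (52.0 to 54.3%) in the control and 55.2% (54.1 to 56.4%) in the CD40 library, while its gene expression differed between them. Cd5l, a secreted scavenger protein of tissue macrophages, stood at 1.68 (1.39 to 2.01) CPM in the control and 71.4 (69.8 to 73.0) in the CD40 library, and at 3.33 (2.96 to 3.73) in the PD1 and 60.9 (59.2 to 62.7) in the combination library. Nos2 (ENSMUSG00000020826, GRCm38 chromosome 11, 78920787 to 78960254), the inducible nitric oxide synthase, was higher with the antibody by log2 ratios of 1.80 and 2.25. Ctsk, a lysosomal protease, was higher by 3.42 and 3.45, Ly6i by 2.73 and 1.63, and Smpdl3b by 1.54 and 1.34. The chemokine gene Pf4 was lower, with log2 ratios of -1.71 and -1.87, the iron carrier Trf -1.74 and -2.13, the matrix gene Fn1 -1.24 and -1.12, and the antiviral gene Rsad2 -1.10 and -1.23. The lipid carrier gene Apoe stood at 2867 and 1014 CPM in the control and CD40 libraries. The leading clusters also differed. Cluster 0 (Spp1, Arg1, Pf4) held 24.5% of the class in the control, cluster 2 (Ace, Adgre4, Treml4) held 20.8% in the CD40 and 21.5% in the combination library, and cluster 1 (Cxcl9, H2-DMb1) held 20.1% in the PD1 library. The Cd5l-expressing cluster 20 had 9, 208, 59 and 126 cells in the control, CD40, PD1 and combination libraries. With every cell given equal weight, Ctsk in mononuclear phagocyte-like cells, CD40 against control, lay at 2.82.

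The fixed gene lists were read in the same class as the median log2 ratio of their members, with the percentile of that median among 10000 random lists of matched expression as a description of these libraries. In CD40 against control, 12 of 12 interferon gamma response genes were higher, with a median of 0.60 (0.57 to 0.62) at percentile 100. Cxcl9 (ENSMUSG00000029417, GRCm38 chromosome 5, 92321347 to 92328079), a chemokine that attracts T cells, stood at 432 (427 to 437) and 737 (732 to 742) CPM. MHC class I presentation had a median of 0.30, with 10 of 10 members higher, and MHC class II presentation -0.080, with all 8 members slightly lower. The suppressive macrophage list (Arg1, Mrc1, Trem2 and others) lay at -0.31, and type I interferon response at -0.58, with 10 of 11 members lower. Costimulation and CD40 signalling lay at 0.34, proliferation at 0.59, inflammatory myeloid at -0.29, T cell chemoattraction at 0.10 and dendritic cell maturation at 0.36. The maturation list holds markers that named the mature dendritic cell-like cells (Ccr7, Fscn1, Ccl22, Il4i1, Socs2 and Cacnb3). Its values in phagocytes, here and below, were thus partly set by the naming. Glycolysis and hypoxia (0.041), dissociation stress (-0.23) and melanoma transcripts (-0.51) served as checks, and the treatment targets list, which holds Cd40, lay at 0.34. In combination against PD1 the interferon gamma median was -0.073, opposite in sign to the first comparison, while the suppressive list lay at -0.36 and type I interferon at -0.46. Without the macrophage-named clusters, the interferon gamma response list in mononuclear phagocyte-like cells, CD40 against control, lay at 0.13 and the costimulation and CD40 signalling list in mononuclear phagocyte-like cells, CD40 against control, turned to -0.40. In the same setting the suppressive macrophage list in mononuclear phagocyte-like cells, CD40 against control, lay at -0.83 and the suppressive macrophage list in mononuclear phagocyte-like cells, combination against PD1, at -1.13. The dendritic cell maturation list in mononuclear phagocyte-like cells, CD40 against control, turned to -0.30 with each library clustered on its own.

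**Figure D2:**
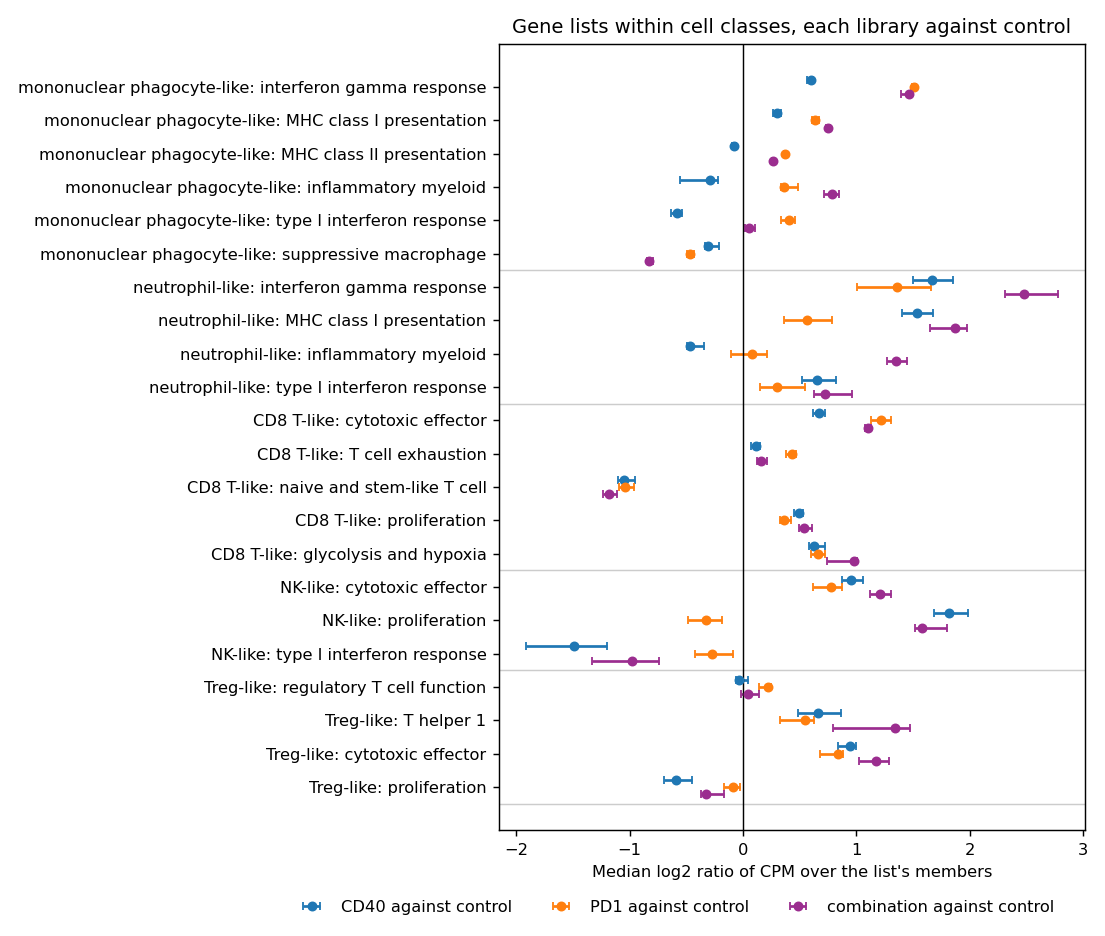
Median log2 ratio of CPM over the members of selected gene lists (horizontal axis) within each class, for the CD40, PD1 and combination libraries against control; error bars are 95% intervals from redrawn counts and cover counting error only. The interferon gamma response list in mononuclear phagocyte-like cells lies at 0.60 for CD40, 1.51 for PD1 and 1.46 for the combination against control.

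In neutrophil-like cells, the interferon-induced GTPase genes Gbp4 and Gbp8 were higher with CD40 antibody. Gbp4 stood at 13.6 (6.77 to 24.3) CPM in the control and 281 (263 to 299) in the CD40 library, and Gbp8 was higher by log2 ratios of 3.83 and 3.78. Ly6i was higher by 5.16 and 3.63. Cluster 29, which shared Ly6i and Ace with the monocytes of cluster 2 and had a median doublet score of 0.149, just below the limit of 0.15, had 9, 52, 11 and 54 cells in the control, CD40, PD1 and combination libraries. Without it, Ly6i in neutrophil-like cells, CD40 against control, lay at 5.05, and the interferon gamma response list in neutrophil-like cells, CD40 against control, at 1.90. The protease inhibitor genes Stfa2 and Cstdc5 were also higher, by at least 4.39 and by 3.94 in CD40 against control, but belong to a family of near-identical genes whose counts are uncertain. Trf (-2.01 and -2.02), the membrane glycoprotein gene Pdpn (-1.73 and -1.82), Slc26a11 (-1.51), Sfxn5 (-1.40) and Peak1 (-1.33) were lower. All 11 measured interferon gamma response genes were higher in CD40 than in control, with a median of 1.67 at percentile 100, and the median was 1.09 (0.86 to 1.30) in combination against PD1. MHC class I presentation lay at 1.54 and type I interferon response at 0.65 in CD40 against control. The class was shallow, with a median of 2195.5 UMIs per cell in the control and 3910 in the CD40 library. Cluster 11 (Cstdc4, S100a9, Cxcl2) was the largest in both, with 50.7% and 63.7% of the class. With predicted doublets kept, the interferon gamma response list in neutrophil-like cells, CD40 against control, lay at 2.74.

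CD8 T-like cells with CD40 antibody had more Gzmk (ENSMUSG00000042385, GRCm38 chromosome 13, 113171608 to 113225908), which encodes a granzyme of effector and memory T cells. It stood at 43.9 (40.0 to 48.0) CPM in the control and 291 (285 to 298) in the CD40 library, and at 101 (97.1 to 106) in the PD1 and 409.8 (404 to 415) in the combination library. Furin, a proprotein convertase, was higher by 1.94 and 2.08, the exchange factor gene Rasgrp2 by 1.42 and 1.84, the integrin gene Itgb7 by 1.39 and 1.75, and the nuclear receptor gene Rora by 1.36 and 1.98. The chemokine gene Ccl1 was lower, with log2 ratios of -3.23 and -2.48, as were Nrgn (-1.74 and -1.73), Srgap3, Adamts6 and the granzyme gene Gzmc (-1.36 and -1.09). In CD40 against control the cytotoxic effector list had a median of 0.67 (0.62 to 0.72), with 12 of 12 members higher, and the T helper 1 list lay at 0.49. The naive and stem-like T cell list (Tcf7, Lef1 and others) lay at -1.05 (-1.11 to -0.95), and T cell exhaustion at 0.12. Cluster T7 (Tcf7, Lef1) held 29.6% of the class in the control, while cluster T2 (Cxcr6, Trbv19) led with 26.3% in the CD40 library. Without cluster T7, the naive and stem-like T cell list in CD8 T-like cells, CD40 against control, lay at -0.094. Rasgrp2 in CD8 T-like cells, CD40 against control, lay at 0.77 with every cell given equal weight.

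Treg-like cells with CD40 antibody had less Nt5e, which encodes the ectonucleotidase CD73, at 67.3 (59.9 to 75.3) CPM in the control and 12.5 (7.73 to 19.1) in the CD40 library and a log2 ratio of -1.54 in combination against PD1. Gem, a small GTPase gene, was higher by 1.67 and 1.53, Serpina3f by 1.41 and 1.43, Ms4a4b by 1.49 and 1.11, and the chromatin organiser gene Satb1 by 1.00 and 1.11. Rad51b, the polymerase gene Pola1 and Ephx1 were lower, at -1.36, -1.25 and -1.04 in CD40 against control. The regulatory T cell function list (Foxp3, Il2ra, Ctla4 and others) lay at -0.031 (-0.059 to 0.041). It holds the markers that named the class (Foxp3, Il2ra, Ikzf2, Ctla4 and Tnfrsf4), so its values here and below were partly set by the naming. T helper 1 genes lay at 0.66 and cytotoxic effector genes at 0.95. The CD8 T cell marker Cd8a rose too, from 26.2 to 166 CPM, and from 15.2 CPM in the PD1 to 97.7 CPM in the combination library, so CD8 T cells among the Treg-like cells were not excluded. Without the cells that had a Cd8a or Cd8b1 UMI, the T helper 1 list in Treg-like cells, CD40 against control, lay at 0.60, the cytotoxic effector list in Treg-like cells, CD40 against control, at 1.34 and Ms4a4b in Treg-like cells, CD40 against control, at 0.71. Cluster T0 (Tnfrsf4, Foxp3, Ctla4) held 81.8% of the class in the control and 85.8% in the CD40 library. With every cell given equal weight, Pola1 in Treg-like cells, CD40 against control, lay at -0.28.

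NK-like cells held a similar share in the control and CD40 libraries but carried more transcripts of cell division. Mki67, a marker of cycling cells, stood at 51.0 (43.8 to 59.1) CPM in the control and 297 (284 to 311) in the CD40 library, and at 44.1 (38.5 to 50.2) in the PD1 and 251 (240.5 to 262) in the combination library. The cyclin gene Ccna2 was higher by 2.45 and 2.69, the histone gene Hist1h1b by 2.93 and 2.69, Gzmk by 3.39 and 3.48, and Gpx8 by 4.67 and 3.05. The transcription regulator genes Aff3 (-2.59 and -2.02) and Bach2 (-1.82 and -1.65) were lower, together with Pmepa1, Parp8 and Fosl2. The proliferation list had medians of 1.81 (1.68 to 1.99) in CD40 against control and 2.08 in combination against PD1, and the cytotoxic effector list 0.95 in the first. The type I interferon response list lay at -1.49. Cluster 26, led by histone genes and Mki67, held 1.35% of NK-like cells in the control, 15.7% in the CD40, 1.43% in the PD1 and 14.3% in the combination library. With each cell thinned to 2000 UMIs and shallower cells left out, an Mki67 UMI was found in 2.18% of NK-like cells in the control and 18.9% in the CD40 library. The corresponding shares of neutrophil-like cells, taken as a background on the untested assumption that they do not divide, were 1.23% (0.149 to 4.36%) and 1.70% (0.852 to 3.02%). In the control 115 neutrophil-like cells were left out as too shallow. The T cell marker Cd3e also rose, from 32.8 to 125 CPM in CD40 against control and from 45.0 to 121 CPM in combination against PD1. Cd8a rose from 1.71 to 28.4 CPM and from 9.99 to 45.1 CPM in the same comparisons. Without the cells that had a Cd3e UMI, the proliferation list in NK-like cells, CD40 against control, lay at 2.31. Before thinning the median depth of NK-like cells was 5635 and 11347 UMIs. With each library clustered on its own, the proliferation list in NK-like cells, CD40 against control, lay at 3.91.

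Across genes, the log2 ratios of the 2 comparisons of the CD40 antibody had a Pearson correlation of 0.72 in mononuclear phagocyte-like cells (10872 genes), 0.44 in neutrophil-like, 0.60 in CD8 T-like, 0.57 in Treg-like and 0.77 in NK-like cells. The comparisons of the PD1 antibody gave 0.73, 0.21, 0.32, 0.19 and 0.074 in the same order. Genes are not independent replicates.

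The PD1 antibody was seen in PD1 against control and in combination against CD40. With it, mononuclear phagocyte-like cells had higher interferon gamma response genes and CD8 T-like cells had higher granzyme and perforin genes, while dendritic cell-like and CD8 T-like shares differed less than with the CD40 antibody. CD8 T-like cells were 1.10-fold higher in PD1 than in control and 1.41-fold higher in combination than in CD40. Treg-like cells had log2 ratios of -0.39 (-0.58 to -0.21) and -0.21 (-0.53 to 0.11), and the second interval does not settle a direction. Over all barcodes, the Treg markers had medians of -0.073 in PD1 against control and 0.28 in combination against CD40. Dendritic cell-like cells were lower in both comparisons, with -0.73 (-0.89 to -0.58) and -0.81 (-1.40 to -0.23). B-like cells lay at -1.07 and -0.67, and NK-like cells at 0.11 and 0.12. Mononuclear phagocyte-like cells were higher in PD1 against control (0.21, 0.15 to 0.27) and lower in combination against CD40 (-0.49, -0.55 to -0.42), and neutrophil-like cells lower (-0.58, -0.84 to -0.33) and higher (0.75, 0.62 to 0.89). Among the phagocytes, monocytes alone lay at 0.69 and -0.078 and macrophages alone at -0.018 and -0.75. With cluster 17, which came almost only from the combination library, left out of both the class and the immune-like cells, the share of neutrophil-like cells, combination against CD40, lay at 0.11, and with it left out of the class alone at 0.015 (-0.13 to 0.16). With each cell named on its own, the share of CD8 T-like cells, PD1 against control, lay at 0.46 against 0.13 in the clusters used here.

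In mononuclear phagocyte-like cells all 12 interferon gamma response genes were higher in PD1 than in control, with a median of 1.51 (1.49 to 1.53) at percentile 100, and the median was 0.92 in combination against CD40. Cxcl9 stood at 1247 (1239 to 1254) CPM in the PD1 library against 432 in the control. Gbp2, an interferon-induced GTPase gene, was higher by 2.04 and 1.24, Socs1, which restrains cytokine signalling, by 1.69 and 1.35, and Nos2 by 1.52 and 1.97. Upp1, a uridine phosphorylase gene, was higher by 2.18 and 1.40, and the actin-binding gene Cnn3 by 2.06 and 1.66. The growth factor gene Igf1 (-1.21 and -1.21) and Pf4 (-1.19 and -1.35) were lower. In PD1 against control, MHC class I presentation lay at 0.64, MHC class II presentation at 0.37, costimulation and CD40 signalling at 0.67 and suppressive macrophage genes at -0.47. Without the macrophage-named clusters, the suppressive macrophage list in mononuclear phagocyte-like cells, PD1 against control, turned to 0.64. The proliferation list in mononuclear phagocyte-like cells, PD1 against control, moved from -0.64 to 0.033 with each library clustered on its own.

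In neutrophil-like cells, Lcn2, an iron-sequestering protein of granules, was higher by 1.78 in PD1 against control and 2.71 in combination against CD40. Nos2 stood at 19.7 (11.3 to 32.0) CPM in the control and 55.8 (39.9 to 76.0) in the PD1 library. Gbp5 (2.34 and 1.43), the adhesion gene Icam1 (1.29 and 1.57) and the chemokine gene Cxcl10 (2.07 and 1.15) were also higher, and Rgs10 (-1.20) and Nol7 (-1.04) lower. The interferon gamma response list lay at 1.35 (1.01 to 1.66) in PD1 against control. Cluster 17, found almost only in the combination library, was led by Lcn2. Without it, Lcn2 in neutrophil-like cells, combination against CD40, lay at 0.94, Nos2 in neutrophil-like cells, combination against CD40, at 1.12 and Icam1 in neutrophil-like cells, combination against CD40, at 0.93. Lcn2 in neutrophil-like cells, PD1 against control, lay at 0.84 with every cell given equal weight.

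In CD8 T-like cells, Gzmb, the main granzyme of killer lymphocytes, stood at 933 (914 to 951) CPM in the control and 3358 (3333 to 3384) in the PD1 library, and at 1267 (1254 to 1281) in the CD40 and 3047 (3032 to 3062) in the combination library. Prf1, which encodes perforin, was higher by 1.68 and 1.01. Gzmd and Gzmf were also higher, by 1.29 and 1.03 in combination against CD40, with uncertain counts because these granzyme genes are close paralogs. St6galnac3, a sialyltransferase gene, was lower, at -1.45 and -1.13. The cytotoxic effector list had medians of 1.22 (1.13 to 1.31) and 0.42, and T cell exhaustion genes lay at 0.43 in PD1 against control. The naive and stem-like T cell list lay at -1.04 in PD1 against control and 0.18 in combination against CD40. Cluster T7 held 29.6% of the class in the control and 14.8% in the PD1 library, and without it the naive and stem-like T cell list in CD8 T-like cells, PD1 against control, lay at -0.68 and the naive and stem-like T cell list in CD8 T-like cells, combination against CD40, at 0.53. Cluster T3 (Gzmf, Gzmd, Prf1) was the largest of the class in the PD1 library, with 27.9%. In Treg-like cells Gem was higher by 1.45 and 1.31, and the regulatory T cell function list lay at 0.22 in PD1 against control. In NK-like cells no gene met the naming rule for the PD1 antibody, the cytotoxic effector list lay at 0.78 and the proliferation list at -0.33 in PD1 against control. With each library clustered on its own, the proliferation list in NK-like cells, PD1 against control, turned to 0.18.

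In the combination library the CD8 T-like and neutrophil-like shares were higher, and the dendritic cell-like and Treg-like shares lower, than in the control. CD8 T-like cells were 3.02-fold higher, a log2 ratio of 1.59 (1.48 to 1.71), and neutrophil-like cells 4.26-fold higher, 2.09 (1.90 to 2.28). Dendritic cell-like cells were 23.0-fold lower, -4.52 (-5.00 to -4.09), and Treg-like cells 3.58-fold lower, -1.84 (-2.10 to -1.58). The Treg-like share lay near that of the CD40 library, and with each cell named on its own the share of Treg-like cells, CD40 against control, lay at -1.36 and the share of Treg-like cells, combination against control, at -1.28. Mononuclear phagocyte-like cells were lower, at 39.5% (38.4 to 40.5%) of immune-like cells. Within the class, macrophages were lower, at a log2 ratio of -0.83, and monocytes higher, at 0.29 (0.18 to 0.41). Cluster 17, neutrophil-like cells with Lcn2, Il1a and Il1b, had 603 cells in the combination library and 5, 13 and 8 in the control, CD40 and PD1 libraries. With it left out of both the class and the immune-like cells, the share of neutrophil-like cells, combination against control, lay at 1.45, and with it left out of the class alone at 1.35 (1.15 to 1.55). The share of dendritic cell-like cells, combination against control, lay between -5.35 with each library clustered on its own and -1.92 with each cell named on its own.

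In mononuclear phagocyte-like cells of the combination library, Nos2 stood at 349 (345 to 354) CPM, against 25.6 (24.4 to 26.8) in the control, 88.9 (87.1 to 90.7) in the CD40 and 73.6 (71.8 to 75.4) in the PD1 library. Cd5l was higher than in the control by 5.18, Ly6i by 3.68, Upp1 by 3.41 and the interferon-induced GTPase gene Iigp1 by 2.72. Retnla, a secreted resistin-like protein gene, had 5009 UMIs in the control, 6 in the CD40, 354 in the PD1 and 0 in the combination library, which at the floor of 3 UMIs gives a log2 ratio of at most -10.86. The lectin gene Mgl2, which cDC2 cells also express, lay at -4.64, Cbr2 at -3.29, Pf4 at -3.06 and Trf at -2.64. All 12 interferon gamma response genes were higher, with a median of 1.46 (1.39 to 1.49). The inflammatory myeloid list (Il1b, Tnf, Nos2 and others) lay at 0.79, MHC class I presentation at 0.75 and suppressive macrophage genes at -0.83 (-0.85 to -0.79). Cluster 15, led by Nos2, held 15.9% of the class in the combination library and had 2 cells in the control. Without the macrophage-named clusters, the interferon gamma response list in mononuclear phagocyte-like cells, combination against control, lay at 0.82, and the suppressive macrophage list in mononuclear phagocyte-like cells, combination against CD40, turned from -0.75 to 0.018. With every cell given equal weight, the costimulation and CD40 signalling list in mononuclear phagocyte-like cells, combination against control, moved from 0.61 to -0.012.

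In neutrophil-like cells of the combination library, the cytokine gene Il1a (ENSMUSG00000027399, GRCm38 chromosome 2, 129299610 to 129309972) stood at 1549.8 (1522 to 1578) CPM, against 29.6 (19.0 to 44.0) in the control, a log2 ratio of 5.71. The acute-phase gene Saa3 had 1 UMI in the control and 3695 in the combination library, a log2 ratio of 7.04 (6.14 to 13.93) taken at the floor of 3 UMIs. The granule genes Ngp and Camp had 1 and 0 UMIs in the control, 2767 and 1999 in the CD40, 1077 and 567 in the PD1 and 2899 and 1787 in the combination library. The class held 811023, 3556151, 716498 and 7608226 UMIs in the same order. Relative to these totals, both granule genes were lower in the combination than in the CD40 and PD1 libraries. With the control at the floor of 3 UMIs, the log2 ratios of Ngp and Camp for combination against control were 6.69 (5.79 to 13.58) and at least 5.99. Csf3, a growth factor gene for neutrophils, had 0 UMIs in the control and 1431 in the combination library, a log2 ratio of at least 5.67. Over the 1123 genes with at least 100 UMIs in each library, the median of the class lay lower in the combination library, and scaling by the median ratio of these genes placed every ratio higher than CPM did, by 0.37 against control, 0.29 against CD40 and 0.34 against PD1. Relative to the median of these genes, lower ratios were thus smaller and higher ratios larger than on CPM. P2rx7, an ATP-gated channel gene, had a log2 ratio of -3.76, and Reps2, Slc26a11, Tex14 and Pip5k1b had -2.86, -2.47, -2.58 and -2.39. The interferon gamma response list lay at 2.48 (2.31 to 2.78), with all 11 members higher, and the inflammatory myeloid list at 1.35. Cluster 17 held 41.2% of the class. Without it Il1a in neutrophil-like cells, combination against control, lay at 2.41, Saa3 in neutrophil-like cells, combination against control, with the control at the floor, at 3.41 and Csf3 in neutrophil-like cells, combination against control, likewise, at 1.04. In the same setting the inflammatory myeloid list in neutrophil-like cells, combination against control, turned to -0.082, and the T cell chemoattraction list in neutrophil-like cells, combination against control, turned from 0.64 to -0.46.

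CD8 T-like cells of the combination library had more Gzmk (3.22, 3.09 to 3.36) and Gzmb (1.71, 1.68 to 1.74) than the control, together with the metallothionein gene Mt1 (1.87), Furin (1.89) and Gzmg (1.90, a paralog with uncertain counts). Ccl1 (-4.32), the calcium pump gene Atp2b2 (-4.10), Lad1 (-3.54), Slc16a11 (-3.15) and the enkephalin gene Penk (-2.42) were lower. Cluster T15, which expressed Ccl1, Xcl1 and Penk, had 106 cells in the control and 18 in the combination library. All 12 cytotoxic effector genes were higher, with a median of 1.10 (1.08 to 1.13), against 0.42 when compared with CD40 alone and 0.065 with PD1 alone. The exhaustion list lay at 0.16 and the naive and stem-like list at -1.18 (-1.23 to -1.11). Cluster T1 (Trbv3, Gzmk, Cxcr3) was the largest of the class, with 22.1%. Without cluster T7, the naive and stem-like T cell list in CD8 T-like cells, combination against control, turned to 0.32.

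Treg-like cells of the combination library had more of the chemokine gene Ccl9 (4.64, 4.01 to 5.35), Gem (2.98), Penk (2.01), Ms4a4b (2.01) and Rasgrp2 (2.33) than the control. Lars2, Ephx1, Cpd, Rad51b and Hivep3 were lower, between -2.02 and -1.56. T helper 1 genes lay at 1.34 and regulatory T cell function genes at 0.040. Cd8a was higher there too (1.90), and without the cells that had a Cd8a or Cd8b1 UMI the T helper 1 list in Treg-like cells, combination against control, lay at 1.33. In NK-like cells of the combination library, Gzmk (4.34), Gpx8 (4.25), the chemokine receptor gene Cx3cr1 (3.05) and Klrg1 (2.82), a receptor of mature NK cells, were higher than in the control, with Hist1h1b at 2.58. The T cell markers Cd3e (32.8 and 121 CPM in the control and combination libraries) and Cd8a (1.71 and 45.1 CPM) rose too. Without the cells that had a Cd3e UMI, Gzmk in NK-like cells, combination against control, lay at 4.13 and Klrg1 in NK-like cells, combination against control, at 2.82. Gzmg, a paralog with uncertain counts, was lower (-2.14; 530, 0, 1 and 289 UMIs in the control, CD40, PD1 and combination libraries), unlike in CD8 T-like cells. The growth factor gene Angpt1 (-3.59), Maml3 (-3.08), Aff3 and Bach2 were also lower. The cytotoxic effector list lay at 1.21 and proliferation at 1.58 (1.52 to 1.80), -0.15 relative to CD40 alone and 2.08 relative to PD1 alone. With each library clustered on its own, the proliferation list in NK-like cells, combination against control, lay at 3.98.

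**Figure D3:**
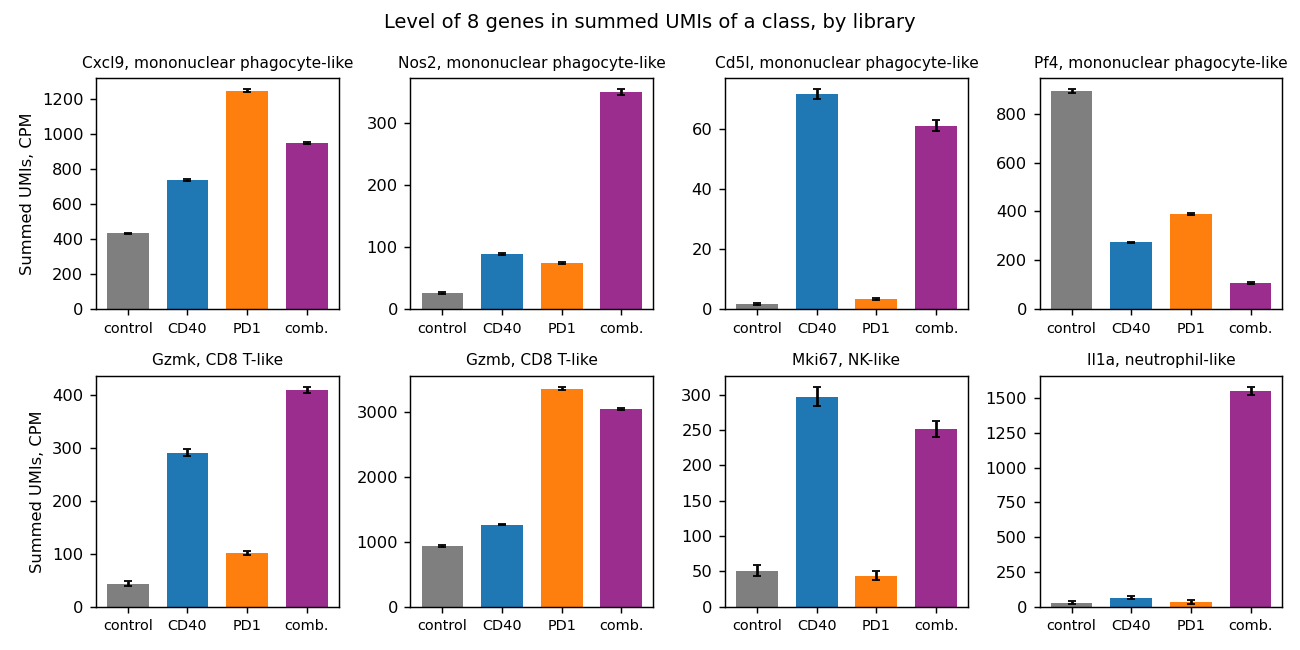
Levels of 8 genes (CPM of summed UMIs, linear axes from 0) within the named class in the control, CD40, PD1 and combination libraries; bars are 1 library each and error bars are exact 95% Poisson intervals for counting error. Nos2 in mononuclear phagocyte-like cells lies at 25.6, 88.9, 73.6 and 349 CPM.

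The targets of the antibodies were measured in the same way. Cd40 (ENSMUSG00000017652, GRCm38 chromosome 2, 165055627 to 165072948) stood at 55.5 (53.7 to 57.2), 70.2 (68.6 to 71.8), 124 (122 to 126) and 113 (110.3 to 115) CPM in mononuclear phagocyte-like cells of the control, CD40, PD1 and combination libraries. Pdcd1 (ENSMUSG00000026285, GRCm38 chromosome 1, 94038305 to 94052553), which encodes PD1, stood at 399 (387 to 411), 453 (445 to 461), 514 (504 to 524) and 469 (463 to 475) CPM in CD8 T-like cells.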

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

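Of the tests below, all were chosen only after the result was seen, except the test of depth by thinning in NK-like cells, whose prediction was written before. None of the differences between comparisons was tested, since each group was 1 library.

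In both libraries with CD40 antibody, dendritic cell-like cells were scarce, and the smaller of the 2 log2 differences in their share was -3.72. Dilution by other classes would lower other shares too. The NK-like share lay at -0.10 in CD40 against control, but NK-like cells carried more cell division transcripts there, so this cannot decide. In the same comparison the B-like, CD4 T-like, Treg-like and pDC-like shares were lower (-2.21, -2.71, -1.63 and -1.46). These falls were smaller than that of the dendritic cell-like share. The mononuclear phagocyte-like, CD8 T-like, neutrophil-like and gamma-delta T-like shares were not lower (0.055, 1.10, 1.34 and 1.15). Dilution as part of the fall thus stays open. Cells that kept their identity under another name would keep their markers, but over all barcodes the dendritic cell markers had a median of -2.36 in CD40 against control and -1.35 in combination against PD1. This argues against a change of name as the whole cause only. The medians were smaller than the falls of the share, but the markers differed widely. In CD40 against control 17 of 18 were lower, down to -6.67 for Cd209a, and Cadm1 was higher at 0.46. The medians therefore do not measure how many cells changed name. With each cell named on its own, the share of dendritic cell-like cells, CD40 against control, lay at -1.44 and the share of dendritic cell-like cells, combination against PD1, at -1.51, so a change of name as part of the fall stays open. The hypothesis that the CD40 antibody lowers intratumoral dendritic cells is consistent with the fall that was left. Loss of their marker genes, death, migration to lymph nodes and loss during sorting were not tested.

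Neutrophil cluster 17 (Lcn2, Il1a, Il1b) had 95.9% of its 629 cells from the combination library. Its median doublet score was 0.0196, against 0.0221 in neutrophil cluster 11, which argues against doublets. Its 10 leading genes had in CD8 T-like cells of that library a median of 0.0880% of their CPM in neutrophil-like cells. These genes were chosen for being high relative to all other cells, CD8 T-like cells included. A low level there was thus partly built in, and the value cannot decide on free RNA. An effect of the combined treatment and a feature of that 1 library or pool of mice cannot be told apart, because there is no other combination library.

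Cell cycle genes were high in NK-like cells with CD40 antibody, with list medians of at least 1.81 in both comparisons. Cd8a rose in NK-like cells from 1.71 to 28.4 CPM in CD40 against control, so some CD8 T cells among them were not excluded. The values argue against CD8 T cells as the cause of the cell cycle difference. The Cd8a level in the CD40 library allows at most 2.80% of the transcripts of NK-like cells to come from CD8 T cells, while the rise of Mki67 would need 92.5%. The values argue against other T cells and NKT cells as the whole cause, since without the cells that had a Cd3e UMI the list medians were 2.31 in CD40 against control and 2.28 in combination against PD1. Greater depth is also argued against, since with cells thinned to 2000 UMIs the share with an Mki67 UMI was 8.67 times that of the control in the CD40 library and 6.43 times that of the PD1 library in the combination library. The hypothesis that more NK cells divide after CD40 antibody is consistent with these values, though it was found and tested on the same data.

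Other results differed in direction between the 2 comparisons of the same antibody. The share of mononuclear phagocyte-like cells had a log2 ratio of 0.21 in PD1 against control and -0.49 in combination against CD40. Monocytes alone were higher in the first (0.69, 0.58 to 0.80), with no settled direction in the second (-0.078, -0.18 to 0.027). Macrophages alone had no settled direction in the first (-0.018, -0.089 to 0.054) and were lower in the second (-0.75, -0.83 to -0.66). The opposite direction thus appeared only in the joined class. The share of neutrophil-like cells had -0.58 and 0.75 in the same comparisons, but 0.015 (-0.13 to 0.16) in the second with cluster 17 left out of the class, so that the opposite direction rested on that cluster. The naive and stem-like T cell list in CD8 T-like cells had -1.04 and 0.18. The interferon gamma response list in mononuclear phagocyte-like cells had 0.60 in CD40 against control and -0.073 in combination against PD1.

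A pair of unnamed clusters, outside the comparisons, held a larger share with treatment than in the control. Cluster 35, cells with few UMIs and with Nos2 and Clec4e, made up 0.193% of kept cells in the combination library (18 cells) and 0 cells elsewhere, where a count of 0 allows at most 0.0482%. Cluster T13, T cells with the heat shock genes Hspa1a and Hspa1b and with Ctla4, made up 1.13% in the CD40, 0.378% in the PD1 and 0.998% in the combination library, against 0.105% in the control.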

How the results depend on the processing

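Each result was computed again with 1 choice altered at a time. The alternatives were written before the data were examined, except those that leave out clusters or cells with Cd8a, Cd8b1 or Cd3e, which were chosen after seeing the data. Of 368 values of 45 class shares, 310 stayed within the counting interval, 57 moved beyond it and 1 turned direction. Of 2423 values of 210 list results, 1879 stayed, 515 moved and 29 turned, and of 699 values of 186 gene results, 540 stayed, 159 moved and 0 turned. The genes were chosen for large ratios in these same data. They were not computed again under other resolutions, separate clustering of each library or thinning. That none turned is therefore not comparable with the counts for shares and lists. A change of sign was counted as turned only for shares and genes whose interval left out 0, and for lists that also lay within the outer 2.5% of the random lists; other values that crossed 0 were counted by their interval. Values below are log2 ratios, in parentheses, under the named alternative, and the cause was not tested. Depth limits neutrophil-like cells most, with a median of 2195.5 UMIs in the control.

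Values that reversed come first, then the leading results that moved; in shortened names CD40, PD1 and combination stand for each against control. At Leiden resolution 0.5, the reversed value was the proliferation list in NK-like cells, PD1 against control (0.0030). With cells thinned before clustering, reversed values were the dendritic cell maturation list in mononuclear phagocyte-like cells, CD40 against control (-0.65), the dendritic cell maturation list in mononuclear phagocyte-like cells, combination against control (-0.39), the MHC class II presentation list in neutrophil-like cells, PD1 against control (0.48), the proliferation list in neutrophil-like cells, CD40 against control (-0.41) and the proliferation list in Treg-like cells, PD1 against control (0.020). With each library clustered on its own, reversed values were the share of pDC-like cells, CD40 against control (0.21), the maturation list in phagocytes, CD40 (-0.30), the proliferation list in mononuclear phagocyte-like cells, PD1 against control (0.033), the proliferation list in mononuclear phagocyte-like cells, combination against control (0.25), the proliferation list in neutrophils, CD40 (-0.24) and the type I interferon response list in CD8 T-like cells, CD40 against control (0.87). Others were the proliferation list in NK cells, PD1 (0.18). With a mean over cells, reversed values were the costimulation and CD40 signalling list in mononuclear phagocyte-like cells, combination against control (-0.012), the T cell chemoattraction list in mononuclear phagocyte-like cells, combination against control (-0.030), the T cell chemoattraction list in neutrophil-like cells, CD40 against control (0.16) and the proliferation list in Treg cells, PD1 (0.011). With predicted doublets kept, reversed values were the costimulation and CD40 signalling list in mononuclear phagocyte-like cells, CD40 against control (-0.11) and the maturation list in phagocytes, CD40 (-0.46). Without cells with a Cd8a or Cd8b1 UMI, the reversed value was the proliferation list in Treg cells, PD1 (0.16). Without cluster 17, reversed values were the inflammatory myeloid list in neutrophil-like cells, combination against control (-0.082) and the T cell chemoattraction list in neutrophil-like cells, combination against control (-0.46). Without cluster 26, the reversed value was the proliferation list in NK cells, PD1 (0.00061). Without cluster T7, the reversed value was the naive and stem-like T cell list in CD8 T-like cells, combination against control (0.32). Without the macrophage-named clusters, reversed values were the costimulation list in phagocytes, CD40 (-0.40), the maturation list in phagocytes, CD40 (-0.72), the suppressive macrophage list in mononuclear phagocyte-like cells, PD1 against control (0.64), the suppressive macrophage list in mononuclear phagocyte-like cells, combination against CD40 (0.018), the chemoattraction list in phagocytes, combination (-0.024) and the proliferation list in phagocytes, combination (1.16). At Leiden resolution 0.5, moved values were the share of CD8 T-like cells, CD40 against control (0.89), the share of CD8 T-like cells, combination against control (1.32), the cytotoxic effector list in CD8 T-like cells, combination against control (1.17), the naive and stem-like T cell list in CD8 T-like cells, CD40 against control (-1.20), the naive and stem-like T cell list in CD8 T-like cells, PD1 against control (-0.92) and combination (-1.31). Others were the proliferation list in NK-like cells, CD40 against control (1.53) and the proliferation list in NK-like cells, combination against control (1.16). At Leiden resolution 2, moved values were the share of CD8 T cells, CD40 (1.23), the share of mononuclear phagocyte-like cells, CD40 against control (-0.020), the share of mononuclear phagocyte-like cells, combination against control (-0.53), the suppressive macrophage list in mononuclear phagocyte-like cells, combination against control (-0.77), the interferon gamma response list in mononuclear phagocyte-like cells, CD40 against control (0.54) and the cytotoxic list in CD8 T cells, combination (1.07). Others were the naive list in CD8 T cells, combination (-1.09). Under the stricter cell filter, moved values were the interferon gamma response list in neutrophil-like cells, CD40 against control (2.47) and the interferon gamma response list in neutrophil-like cells, combination against control (3.12). With cells thinned before clustering, moved values were the interferon gamma list in neutrophils, CD40 (1.94), the proliferation list in NK cells, CD40 (2.39) and combination (2.31). With each cell named on its own, moved values were the share of CD8 T cells, CD40 (1.57), the share of CD8 T-like cells, PD1 against control (0.46), combination (2.02), the share of Treg-like cells, CD40 against control (-1.36), the share of Treg-like cells, combination against control (-1.28) and the share of phagocytes, combination (-0.50). Others were the share of dendritic cell-like cells, CD40 against control (-1.44), the share of dendritic cell-like cells, PD1 against control (-0.41) and the share of dendritic cell-like cells, combination against control (-1.92). With each library clustered on its own, moved values were the share of CD8 T cells, CD40 (1.46), PD1 (0.45), combination (1.83), the share of phagocytes, CD40 (-0.094), the share of dendritic cells, CD40 (-4.71) and combination (-5.35). Others were the interferon gamma list in phagocytes, CD40 (0.55), the cytotoxic effector list in CD8 T-like cells, CD40 against control (0.62), combination (0.92), the naive list in CD8 T cells, CD40 (-0.70), PD1 (-0.82) and combination (-0.79). Then came the proliferation list in NK cells, CD40 (3.91) and combination (3.98). With a mean over cells, moved values were the suppressive list in phagocytes, combination (-1.04), the interferon gamma list in phagocytes, CD40 (0.51), the interferon gamma response list in mononuclear phagocyte-like cells, PD1 against control (1.47), the interferon gamma response list in mononuclear phagocyte-like cells, combination against control (1.36), the interferon gamma list in neutrophils, CD40 (1.95) and combination (2.99). Others were the cytotoxic list in CD8 T cells, CD40 (0.86), the cytotoxic effector list in CD8 T-like cells, PD1 against control (1.02), combination (1.24), the naive list in CD8 T cells, CD40 (-1.40), PD1 (-0.76) and combination (-1.58). Then came the proliferation list in NK cells, CD40 (2.60), PD1 (-0.16) and combination (2.60). With median-ratio scaling, moved values were the suppressive list in phagocytes, PD1 (-0.41), combination (-0.78), the interferon gamma list in phagocytes, PD1 (1.57), combination (1.51) and the interferon gamma list in neutrophils, combination (2.84). With predicted doublets kept, moved values were the interferon gamma list in neutrophils, CD40 (2.74), the interferon gamma response list in neutrophil-like cells, PD1 against control (2.00), combination (3.15), the cytotoxic list in CD8 T cells, combination (1.07) and the proliferation list in NK cells, PD1 (-0.50). Without cells with a Cd3e UMI, moved values were the proliferation list in NK cells, CD40 (2.31), PD1 (-0.12) and combination (2.26). Without cluster 17, moved values were the share of neutrophil-like cells, combination against control (1.45) and the interferon gamma list in neutrophils, combination (2.96). Without cluster 26, moved values were the proliferation list in NK cells, CD40 (1.51) and combination (1.17). Without cluster 29, moved values were the interferon gamma list in neutrophils, CD40 (1.90) and combination (2.89). Without cluster T7, moved values were the cytotoxic list in CD8 T cells, CD40 (0.52), PD1 (1.09), combination (0.88), the naive list in CD8 T cells, CD40 (-0.094) and PD1 (-0.68). Without the macrophage-named clusters, moved values were the suppressive macrophage list in mononuclear phagocyte-like cells, CD40 against control (-0.83), combination (-0.71), the interferon gamma list in phagocytes, CD40 (0.13), PD1 (1.15) and combination (0.82). Without the monocyte-named clusters, moved values were the suppressive list in phagocytes, PD1 (-0.29), combination (-0.58), the interferon gamma list in phagocytes, CD40 (0.88) and combination (1.58).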

Other observations

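The T cell receptor beta variable segments of CD8 T-like cells differed in their use between libraries, and those named here were chosen after their values were seen. In the combination library Trbv3 was found in 21.3% and Trbv19 in 19.5% of the 2858 cells with at least 3 UMIs of their leading segment, against 8.39% and 7.14% of 644 cells in the control. In the CD40 library these were 11.6% and 15.2% of 1655 cells. In the PD1 library, Trbv1 (ENSMUSG00000076461, GRCm38 chromosome 6, 40891229 to 40891885) stood at 17.3% and Trbv5 at 16.6% of 943 cells, against 3.88% and 1.24% in the control. Other segments were more frequent in the control, where Trbv2 stood at 16.5%, against 5.50%, 5.83% and 3.04% in the CD40, PD1 and combination libraries. Trbv23 stood at 8.54% in the control, against 0.106% in the PD1 and 0.0350% in the combination library. The effective number of segments (inverse Simpson index) was 12.9, 12.6, 11.0 and 8.75 in the control, CD40, PD1 and combination libraries. A segment is shared by many clones, and a large clone in 1 of the 6 pooled mice would move these shares.

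Over all barcodes, without any naming of cells, Flt3, a growth factor receptor of dendritic cells, stood at 28.5 (27.5 to 29.4), 1.68 (1.48 to 1.89), 13.2 (12.6 to 13.8) and 1.07 (0.916 to 1.24) CPM in the control, CD40, PD1 and combination libraries. Xcr1, the receptor of cDC1 cells, stood at 13.1, 0.446, 8.23 and 0.643 CPM, and Ccr7, which guides cells to lymph nodes, at 135, 16.5, 52.4 and 20.1 CPM. The cDC1 marker Clec9a stood at 21.7, 2.64, 20.8 and 4.20 CPM. These genes fell further than the median of the 18 dendritic cell markers, which was -2.36 in CD40 against control. Among the others, Cadm1 was higher (49.2 and 67.7 CPM in the control and CD40 libraries) and Itgax differed less (69.1 and 58.8 CPM). Macrophages with type I interferon genes (Ifit1, Rsad2), cluster 23, numbered 141, 18, 153 and 19 cells. In CD8 T-like cells, the glycolysis and hypoxia list lay at 0.63, 0.67 and 0.98 for CD40, PD1 and combination against control. After thinning to 2000 UMIs, with shallower cells left out, an Mki67 UMI was found in 11.2%, 19.1%, 17.5% and 20.9% of CD8 T-like cells in the control, CD40, PD1 and combination libraries.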
